A study of Mus musculus with 12 samples.

How the data were processed

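RNA was isolated from mouse small intestine with a column kit (RNeasy Micro), and libraries were made with a TruSeq RNA kit and sequenced on a NextSeq 500 with paired reads of 36 cycles, per the labels' protocols. Tamoxifen, which activates the Cre recombinase, was given as 2 injections of 80 mg/kg 24 hours apart, per the labels' protocols. The deposited table holds whole-number counts per gene for 12 libraries, not normalized. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.4, HISAT2 2.1.0 and featureCounts 1.6.4, and the genome build GRCm38, without stating the role or settings of each. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from genes with near-identical copies (ribosomal protein genes and their pseudogenes, defensins, Reg3 genes, immunoglobulin genes, gasdermin C genes, H2 genes, Eif3j1 and Eif3j2) and from antisense neighbours can therefore be split or lost in ways that these counts do not show. Reads this short make that more common.

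Libraries were assigned to groups by the sample titles and genotypes. The table held 55421 gene identifiers, of which 55154 matched GENCODE release M21 (GRCm38), the source of symbols and coordinates here, and 267 did not. The latter held 0.00226% of all counts. Library totals were 10483112 to 21298301 counts. Averaged over genes, counting error was small beside the spread between libraries (chi-square per gene of 18.4 to 53.6 within groups), which was not examined by expression level. Intervals of counting error were not used, since the tests rest on the spread between libraries.

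Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling factors, and a quasi-likelihood model (glmQLFit without the legacy option, glmQLFTest) of all 12 libraries with 1 mean per group, which gives the groups a shared estimate of the spread. Of the genes 20439 were at 0 in all libraries and 17394 passed the filter. The 3 contrasts were Apc against WT, Apc Eif3h against Apc and Apc Eif3h against WT, with Benjamini-Hochberg adjustment over all genes tested in each and calls at an adjusted p below 0.05. Standard errors of log2 fold changes were approximated as the absolute log2 fold change divided by the square root of the F statistic. Levels per library are CPM after TMM scaling, as mean ± SD of 4 libraries, and scores and principal components used log2 CPM with a prior count of 2. A list's score in a library is the mean over its members of log2 CPM centred per gene.

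The groups, tests, covariates, alternatives, gene lists and the rule for named genes were set before the data were examined. The rule named Eif3h and Apc, the 10 highest and 10 lowest log2 fold changes per contrast (5 and 5 for Apc Eif3h against WT), and up to 3 called members of each list with the smallest p. The highest and lowest were taken among called genes whose libraries separated the groups and whose mean log2 CPM was 1 or more, leaving out predicted models, immunoglobulin and T cell receptor segments and sex-linked genes. All members of a count of 5 or fewer could also be named. The text uses part of these names, and genes named outside the rule are said to be so.

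The 36 gene lists were Wnt pathway targets, stem cell markers, cell cycle, markers of enterocytes, Paneth, goblet, enteroendocrine and tuft cells, fetal-like and YAP-linked genes, and the integrated stress response. Others were unfolded protein response, p53 targets, eIF3 subunits, other initiation factors, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, interferon response, and antimicrobial and inflammatory genes. The rest were markers of T cells, B and plasma cells, macrophages and neutrophils, mast cells, fibroblasts, smooth muscle, endothelium, and neurons and glia, proximal and distal small intestine, pancreatic acinar, mitochondrially encoded, haemoglobin, immediate early and sex-linked genes. On these lists 20 symbols had no match in the table. Each list with at least 3 tested members was compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. The report gives the adjusted p with an estimated correlation for each called list. The 2 lists that kept their call in Apc against WT were Wnt targets and stem cell markers, the 1 in Apc Eif3h against WT was Wnt targets, and there were 0 in Apc Eif3h against Apc.

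The procedure was checked on counts simulated from the means and library sizes of these samples. At log2 fold changes of 0.5, 1 and 2, 11.9%, 67.2% and 89.4% of changed genes were recovered for Apc against WT among 17233 genes with 3 false calls. The shares were 10.4%, 58.2% and 87.9% for Apc Eif3h against Apc among 17248 genes with 6 false calls, and 13.4%, 47.8% and 95.5% for Apc Eif3h against WT among 17228 genes with 4 false calls. Small changes can therefore be missed at this depth and number of libraries. Besides the ribosomal protein list, 67, 67 and 66 genes were changed at these sizes, and fewer genes changed than were called in the data. The Benjamini-Hochberg threshold is stricter when fewer genes change, so these shares may understate the recovery in the data. No list of unchanged genes was called, and the ribosomal protein list, raised by 0.5, was called in each contrast. Genes were simulated independently of each other, whereas the estimated correlation of ribosomal protein genes was 0.754 in Apc Eif3h against Apc. The simulation therefore does not check list calls where genes of a list move together.

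Alternatives were RLE factors, library totals as the only scaling, no filter, a stricter filter (CPM of 1 in at least 4 libraries), and DESeq2 1.42.0. Further ones were a fit of only the 2 groups compared, the replicate number as a block with TMM or RLE factors, sex as a covariate, male libraries only, leaving out each library in turn, a fold change above 2, and the list tests named above. Score differences between groups were tested by exact two-sided permutation over all 70 arrangements of 8 libraries. Lists were compared with 10000 random lists matched on mean expression and on length, with exonic lengths from GENCODE M21 through GenomicRanges 1.54.1. The genes of a random list were drawn independently of each other. Values of 2 single genes are not reported here.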

Results

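Gene-level RNA sequencing counts were obtained from mouse small intestine in 12 libraries, 4 in each of 3 groups. The groups were wild type (WT), mice with floxed Apc alleles and a tamoxifen-inducible Cre recombinase under the villin promoter, which is active in gut epithelium (called Apc here), and mice with this Cre and floxed alleles of both Apc and Eif3h (called Apc Eif3h). Apc encodes a scaffold of the complex that degrades beta-catenin and so restrains Wnt signalling, and Eif3h encodes subunit h of the translation initiation factor eIF3. The question of the series was how expression in the intestine differs with and without each deficiency. Library totals lay between 10483112 and 21298301 counts. They were 13915889 to 14589963 in WT, 10483112 to 18621953 in Apc and 14221414 to 21298301 in Apc Eif3h. WT and Apc each held 3 males and 1 female, and all 4 Apc Eif3h libraries were from males. The sample labels give day 7 for WT and day 4 for the other 2 groups, whereas the treatment text gives harvest after 7 days throughout, so genotype and day cannot be separated in comparisons with WT. Apc Eif3h against Apc is matched for day by the labels. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be partly technical.

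Eif3h transcripts were lower in every Apc Eif3h library than in any other library. The gene (ENSMUSG00000022312, GRCm38 chromosome 15, 51786558 to 51865523, minus strand) was at 134 ± 6.60 CPM (counts scaled to library size; mean ± SD, n = 4) in WT, 166 ± 7.01 in Apc and 37.99 ± 13.4 in Apc Eif3h. It fell 4.39-fold from Apc to Apc Eif3h (log2 fold change -2.13, SE 0.19, adjusted p = 0.000405) and by 1.82 on the log2 scale from WT to Apc Eif3h (SE 0.19, adjusted p = 1.1e-05). The 4 Apc Eif3h libraries were at 28.27, 43.13, 54.6 and 25.94 CPM. These counts do not separate incomplete deletion from transcripts of cells without Cre activity, in the highest of them or the others. Apc against WT gave 0.31 for Eif3h (SE 0.18, adjusted p = 0.173), which passed the test with library totals as the only scaling (0.0182) and in a fit of the 2 groups alone (0.00294). Apc transcripts (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552, plus strand) were at 94.2 ± 5.02 CPM in WT, 114 ± 6.96 in Apc and 105 ± 12.01 in Apc Eif3h. The rise in Apc over WT was 0.28 (SE 0.09, adjusted p = 0.0177) and was lost without WT replicate 1 (0.0526) or Apc replicate 4 (0.0577). Apc Eif3h differed from Apc by -0.12 (adjusted p = 0.427) and from WT by 0.16 (adjusted p = 0.142, but 0.00928 with library totals only and 0.0387 without Apc Eif3h replicate 3). Whole-gene counts need not show the loss of a floxed exon, and cells outside the epithelium keep both alleles.

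**Figure D1:**
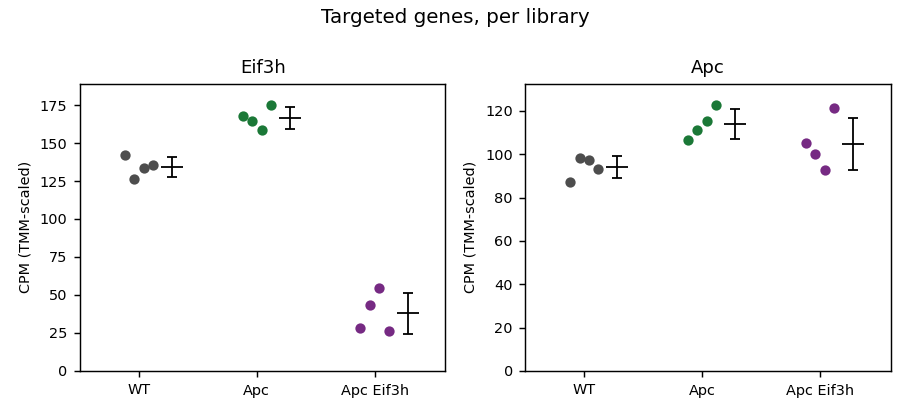
Eif3h (left) and Apc (right) in CPM after TMM scaling, one point per library in replicate order, with the group mean and SD as a bar beside them. Eif3h lies between 25.94 and 54.6 in the 4 Apc Eif3h libraries and between 126.1 and 142.2 in WT, while Apc transcripts overlap between Apc and Apc Eif3h.

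The first principal component of log2 CPM held 51.1% of the variance and the second 11.1%. Apc Eif3h replicate 2 lay at 61.7 on the second component, where no other library exceeded 18.72, and it carried the B cell genes Ighm at 462 and Cd79a at 83.8 CPM. In the other 3 Apc Eif3h libraries Ighm was at 8.56 to 10.7 CPM. Cytosolic ribosomal protein genes took 1.07% ± 0.0621 of counts in WT, 1.95% ± 0.179 in Apc and 2.95% ± 0.532 in Apc Eif3h (mean ± SD, n = 4). Mitochondrially encoded genes took 5.03% ± 0.383, 4.16% ± 0.341 and 3.82% ± 0.603, led in every library by mt-Co1. Xist was at 358 CPM in WT replicate 4 and 701 CPM in Apc replicate 1, the 2 libraries labelled female, and at 1.31 CPM or lower in the rest. No replicate pair agreed within sampling noise: chi-square per gene was 18.4 to 53.6 over the 18 pairs.

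Against WT, Apc libraries held higher levels of Wnt targets (20 of 25 rose; adjusted p = 0.00104 with an estimated correlation) and stem cell markers (20 of 20 rose; adjusted p = 0.0104 with an estimated correlation). Msx1, a homeobox transcription factor, rose by 5.90 on the log2 scale (SE 0.39, adjusted p = 1.8e-06), from 0.525 ± 0.348 to 31.8 ± 4.19 CPM (n = 4 per group). Notum, a secreted Wnt inhibitor, rose by 4.20 (SE 0.42, adjusted p = 1.96e-05), from 0.594 ± 0.278 to 11.2 ± 3.27 CPM. The secreted lectin Reg1 fell by 4.51 (SE 0.73, adjusted p = 0.000336), from 548 ± 289 to 24.0 ± 10.04 CPM, and the cytochrome P450 gene Cyp3a11 fell by 3.43 (SE 0.59, adjusted p = 0.000482), from 1278 ± 236 to 118 ± 67.4 CPM.

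Of 17394 genes tested, 4820 were higher and 4192 lower in Apc at an adjusted p below 0.05 (edgeR, Benjamini-Hochberg), together 9012 genes or 51.8%. More than a 2-fold change was seen in 1627 of those higher and 1137 of those lower. Higher genes made up 53.5% of the calls with TMM factors and 74.0% with library totals only, which shifted the median log2 fold change of all genes to 0.221. The other genes with the highest changes included Pla2g5, a secreted phospholipase (5.80, SE 0.30, adjusted p = 3.68e-07), and the ETS transcription factor Etv4 (4.71, SE 0.27, adjusted p = 1.22e-06). Also among them were the ferric reductase Cybrd1 (4.57, SE 0.74, adjusted p = 0.000338) and the lipoprotein receptor Lrp8 (3.73, SE 0.39, adjusted p = 2.17e-05). Atg9b (5.86), Dok7 (4.14), Epop (4.07) and Mboat1 (3.68) completed the 10 highest. The 10 lowest also held Cyp2b10, another P450 gene (-3.59, SE 0.60, adjusted p = 0.000443), the glucuronosyltransferase Ugt2b5 (-4.17, SE 0.73, adjusted p = 0.000577), the carboxylesterase Ces2a (-3.65) and the glutathione transferase Gstm3 (-3.49). The alcohol dehydrogenase Adh4 (-3.63), Akr1b7 (-3.70), the ubiquitin-like Ubd (-4.17) and the proton channel Otop3 (-4.02) made up the remainder. All 20 kept their call in each fit that left out 1 library.

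Wnt pathway targets rose as a group. Of 25 tested members 20 rose and 2 fell (20 and 3 adjusted over the list alone), with a median log2 fold change of 2.18 (camera adjusted p = 6.21e-19, and adjusted p = 0.00104 with an estimated correlation). Sox9 rose by 2.99 (SE 0.19, adjusted p = 1.55e-06), Rnf43 by 2.18 (SE 0.14, adjusted p = 1.55e-06) and Ascl2 by 2.92 (SE 0.19, adjusted p = 1.59e-06). The members that fell were Dkk2 (-1.08, adjusted p = 0.00823) and Dkk3 (-0.61, adjusted p = 0.000469), both of the Dickkopf family of secreted proteins. All 20 intestinal stem cell markers rose (20 adjusted over the list alone), with a median of 2.03 (camera adjusted p = 1.29e-27, and adjusted p = 0.0104 with an estimated correlation), among them Cdca7 at 2.05 (SE 0.13, adjusted p = 1.8e-06). The lists share 5 genes. Cell cycle genes rose in 37 of 38 members (38 adjusted over the list alone; median 1.44), including cyclin B1 (Ccnb1, 1.75, SE 0.13), Cdk1 (1.48, SE 0.13) and the replication licensing gene Mcm2 (1.84, SE 0.16). Their camera adjusted p was 1.29e-27, but the adjusted p = 0.348 with an estimated correlation.

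Genes of the translation machinery rose. All 44 ribosome biogenesis factors were higher in Apc (44 adjusted over the list alone; median 1.51; camera adjusted p = 2.45e-33, adjusted p = 0.348 with an estimated correlation), with Gar1 at 1.77 (SE 0.14) and fibrillarin (Fbl) at 1.58 (SE 0.13). Cytosolic ribosomal protein genes rose in 75 of 79 members and 76 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 3.27e-15, adjusted p = 0.497 with an estimated correlation). Rpl11 rose by 0.87 (SE 0.10, adjusted p = 3.16e-05) and Rps2 by 1.12 (SE 0.13, adjusted p = 3.25e-05). Many ribosomal protein genes have processed pseudogenes of near-identical sequence, so their single values are uncertain. Of 14 eIF3 subunits 11 rose and none fell, also adjusted over the list alone (median 0.68; camera adjusted p = 4.86e-06, adjusted p = 0.42 with an estimated correlation), led by Eif3b at 0.99 (SE 0.11, adjusted p = 3.51e-05). Other initiation factors rose in 28 of 35 members, the same number as adjusted over the list alone, and none fell (median 0.52; camera adjusted p = 1.95e-07, adjusted p = 0.42 with an estimated correlation). A member fell without WT replicate 1 and without WT replicate 2. Eif4a1, a helicase of the initiation complex, rose by 0.99 (SE 0.09) and Eif2s1 by 1.19 (SE 0.12). Integrated stress response targets rose in 16 of 33 members and fell in 4 (16 and 4 adjusted over the list alone; median 0.42; camera adjusted p = 0.000163, adjusted p = 0.421 with an estimated correlation). Gars (1.51, SE 0.09), Slc7a5 (2.49, SE 0.21) and Phgdh (2.94, SE 0.26), which act in tRNA charging, amino acid transport and serine synthesis, were higher.

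Markers of differentiated epithelium were lower in Apc. Absorptive enterocyte markers fell in 23 of 30 members (23 adjusted over the list alone; median -1.02; camera adjusted p = 4.22e-09, adjusted p = 0.42 with an estimated correlation). Among them were the lipid handling genes Mttp at -1.29 (SE 0.20, adjusted p = 0.000275), Dgat1 at -1.16 (SE 0.18, adjusted p = 0.000282) and Apoc3 at -1.86 (SE 0.30, adjusted p = 0.000352). Of 18 goblet cell markers 10 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00225, adjusted p = 0.55 with an estimated correlation), with Clca1 at -1.41 (SE 0.23). On this list 2 rose without WT replicate 1, WT replicate 3 or Apc replicate 4. Enteroendocrine markers fell in 15 of 21 members and rose in 1, counts that were unaltered adjusted over the list alone (median -0.82; camera adjusted p = 0.000367, adjusted p = 0.455 with an estimated correlation). The incretin gene Gip fell by 1.71 (SE 0.22, adjusted p = 7.54e-05), while Neurog3, the transcription factor of endocrine progenitors, rose by 1.59 (SE 0.21, adjusted p = 9.14e-05). Tuft cell markers fell in 13 of 15 members (13 adjusted over the list alone; median -1.06; camera adjusted p = 0.000128, adjusted p = 0.421 with an estimated correlation), including the leukotriene synthesis genes Ltc4s (-1.42, SE 0.23) and Alox5 (-1.13, SE 0.19). Paneth cell markers did not pass the list test (camera adjusted p = 0.0936), but did without WT replicate 2 (0.0212), WT replicate 3 (0.0242), Apc replicate 1 (0.0417) or Apc replicate 4 (0.0368). Pla2g2a (2.93, SE 0.42), Mmp7 (2.30, SE 0.53) and Habp2 (1.59, SE 0.43) were the 3 of 14 that rose, also adjusted over the list alone.

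Lipid, mitochondrial and secretory pathway genes moved in different directions. Fatty acid oxidation genes fell in 16 of 24 members and rose in 2 (18 and 2 adjusted over the list alone; median -0.60; camera adjusted p = 0.000163, adjusted p = 0.511 with an estimated correlation). Acadm, an acyl-CoA dehydrogenase, was at -0.85 (SE 0.13) and Acot1, an acyl-CoA thioesterase, at 1.44 (SE 0.25). Nuclear-encoded oxidative phosphorylation genes fell in 31 of 50 members (35 adjusted over the list alone; median -0.34; camera adjusted p = 2.27e-06, adjusted p = 0.563 with an estimated correlation), for example Sdhb at -0.68 (SE 0.12, adjusted p = 0.00076). Mitochondrially encoded genes, whose share of counts was also lower, fell in 7 of 13 members (7 adjusted over the list alone; median -0.55; camera adjusted p = 0.00103, adjusted p = 0.511 with an estimated correlation), with mt-Co3 at -0.61 (SE 0.13). Cholesterol synthesis genes rose in 14 of 25 members and fell in 3 (17 and 3 adjusted over the list alone; median 0.54; camera adjusted p = 0.000223, adjusted p = 0.42 with an estimated correlation). Unfolded protein response genes fell in 11 of 25 members and rose in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0112, adjusted p = 0.564 with an estimated correlation). Edem1 (-0.69, SE 0.11) and Xbp1 (-0.61, SE 0.12) fell, but the list's median of -0.21 turned to 0.0225 with library totals only, and its call was lost without WT replicate 1 (0.0917, median -0.13, with 3 members higher). Without WT replicate 2 the median was -0.32. No member of that list rose without any 1 of the other 7 libraries.

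Immune and stromal markers were lower in Apc. T cell and cytotoxic markers fell in 18 of 21 members (19 adjusted over the list alone; median -1.49; camera adjusted p = 2e-05, adjusted p = 0.511 with an estimated correlation). Granzyme A (Gzma) was at -1.75 (SE 0.30, adjusted p = 0.000495) and the chemokine Ccl5 at -1.83 (SE 0.33, adjusted p = 0.000699). Interferon response genes fell in 16 of 34 members (16 adjusted over the list alone; median -0.70; camera adjusted p = 0.000128, adjusted p = 0.55 with an estimated correlation). They included the antigen presentation gene H2-K1 at -1.21 (SE 0.17) and Gbp2 at -1.55 (SE 0.25), and without WT replicate 1 the median was -0.46 and 1 member rose. Macrophage and neutrophil markers fell in 12 of 19 members (12 adjusted over the list alone; camera adjusted p = 0.00129, adjusted p = 0.55 with an estimated correlation), for example Adgre1 at -0.99 (SE 0.23). Epithelial antimicrobial and inflammatory genes fell in 10 of 21 members (10 adjusted over the list alone; camera adjusted p = 0.0121, adjusted p = 0.42 with an estimated correlation), with the chemokine Ccl25 at -1.48 (SE 0.26) and the immunoglobulin receptor Pigr at -1.55 (SE 0.31). None of them rose, against 1 without WT replicate 3, Apc replicate 3 or Apc replicate 4 and 2 without Apc replicate 2. Smooth muscle markers fell in 9 of 15 members (10 adjusted over the list alone; camera adjusted p = 0.00343, adjusted p = 0.511 with an estimated correlation), with Mylk at -0.84 (SE 0.15). Enteric neuron and glia markers fell in 10 of 15 (10 adjusted over the list alone; camera adjusted p = 0.000921, adjusted p = 0.42 with an estimated correlation), with Uchl1 at -0.93 (SE 0.13). Fibroblast markers fell in 6 of 20 members (6 adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.564 with an estimated correlation). Endothelial markers fell in 7 of 15 (5 adjusted over the list alone; camera adjusted p = 0.0186, adjusted p = 0.572 with an estimated correlation). Both calls were lost without WT replicate 1 (0.0778 and 0.0852, each then with 1 member higher). Col14a1 was at -1.03 (SE 0.15), decorin (Dcn) at -0.70 (SE 0.17) and the endothelial junction gene Cldn5 at -1.80 (SE 0.33).

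The remaining lists did not pass the test in Apc against WT. Of 23 fetal-like and YAP-linked genes 10 rose and 5 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.0567), with Krt7 at 1.40 (SE 0.12) and Areg at 1.88 (SE 0.20). The list passed without WT replicate 1 (0.0457), WT replicate 3 (0.0288, with 3 lower), WT replicate 4 (0.0302), Apc replicate 2 (0.0251) or Apc replicate 3 (0.0247, with 2 lower). Among 25 p53 targets 5 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.743), with Gtse1 at 1.99 (SE 0.24) and the death receptor Fas at -1.53 (SE 0.19), and without Apc replicate 3 the counts were 8 and 5. B and plasma cell markers fell in 3 of 12 members, none adjusted over the list alone (camera adjusted p = 0.0818, but 0.0379 without WT replicate 3 and 0.0233 without Apc replicate 3). The 3 members, Jchain (-1.27), Igkc (-1.40) and Igha (-1.36), lost their calls without WT replicate 1 (0.113, 0.122 and 0.135), Apc replicate 1 (0.0725, 0.0742 and 0.0831), Apc replicate 2 (0.0562, 0.0552 and 0.0635) or Apc replicate 4 (0.0712, 0.0747 and 0.0801). Proximal small intestine markers rose in 2 and fell in 6 of 11 members (2 and 7 adjusted over the list alone; camera adjusted p = 0.115), with the iron exporter Slc40a1 at 3.33 (SE 0.46). Distal markers rose in 1 and fell in 4 of 11 (1 and 4 adjusted over the list alone; camera adjusted p = 0.0886), with the bile acid transporter subunit Slc51b at -1.99 (SE 0.24). Immediate early genes rose in 4 and fell in 4 of 21 members (3 and 4 adjusted over the list alone; camera adjusted p = 0.993; 2 higher without Apc replicate 4), with Egr1 at 1.95 (SE 0.25) and Zfp36 at -0.83 (SE 0.18). Of 4 mast cell, 6 haemoglobin and 5 sex-linked genes 0 were called, also adjusted over the list alone (camera adjusted p = 0.613, 0.96 and 0.96), except that 1 sex-linked gene was called without WT replicate 4 and 1 without Apc replicate 1. Of 4 pancreatic acinar genes 1 rose and 1 fell (camera adjusted p = 0.993), and none rose without WT replicate 1, 3 or 4 or Apc replicate 1, 2 or 4. The p53, haemoglobin and sex-linked lists had a positive median and a test direction of lower, and the acinar list a median of 0.34 and a mean of -0.07.

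**Figure D2:**
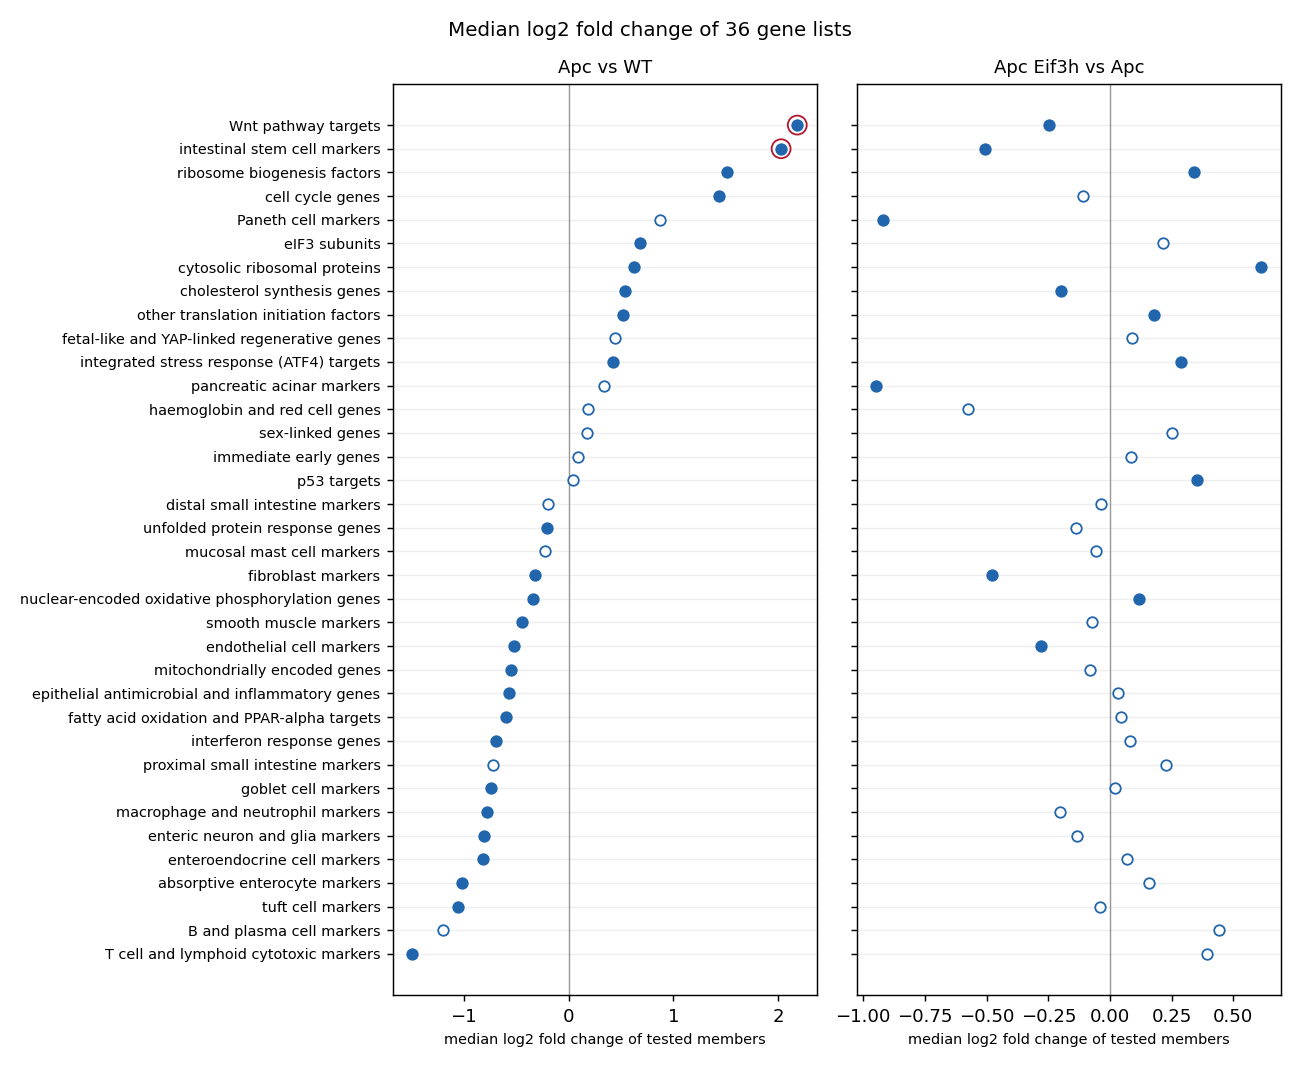
Median log2 fold change of the tested members of each of 36 gene lists, for Apc against WT (left) and Apc Eif3h against Apc (right). Filled points are lists with a camera adjusted p below 0.05, open points are the others, and a red ring marks the 2 lists, Wnt targets (2.18) and stem cell markers (2.03) in Apc against WT, that also passed with an estimated correlation.

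Apc Eif3h and Apc, both labelled day 4, differed less. The noncoding transcript Zfas1, a host of small nucleolar RNAs, rose 3.41-fold (log2 1.77, SE 0.14, adjusted p = 0.00021), from 80.0 ± 5.08 to 273 ± 60.6 CPM (n = 4 per group), and was at 53.9 ± 3.79 in WT. The transcription factors Atf5 (1.37, SE 0.16, adjusted p = 0.00167) and Atf4 (0.83, SE 0.10, adjusted p = 0.00172), which act in the integrated stress response, rose from 24.5 ± 4.18 to 63.5 ± 13.4 and from 213 ± 14.8 to 379 ± 40.4 CPM. Lgr5, a receptor that marks intestinal stem cells, fell by 1.19 (SE 0.22, adjusted p = 0.00974), from 55.9 ± 7.19 to 24.4 ± 6.29 CPM, with WT at 10.6 ± 3.51. Cytosolic ribosomal protein genes were higher by a median of 0.61 on the log2 scale, with 69 of 79 called (camera adjusted p = 1.18e-61, but adjusted p = 0.245 with an estimated correlation).

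At an adjusted p below 0.05, 743 genes were higher and 483 lower in Apc Eif3h, together 1226 or 7.05% of the genes tested. A change of more than 2-fold was seen in 77 and 138 of them. Higher genes made up 60.6% of the calls, and 49.8% with library totals only. Both counts moved with single libraries: 422 higher and 285 lower without Apc replicate 2, 242 and 164 without Apc replicate 3, and 451 and 302 without Apc replicate 4. They were 418 and 283 without Apc Eif3h replicate 1, 418 and 243 without Apc Eif3h replicate 2, and 461 and 249 without Apc Eif3h replicate 4. Without Apc replicate 1 the lower count was 284, and without Apc Eif3h replicate 3 the higher count was 1152. Of the 10 highest and 10 lowest genes, Eif3h among them, 10 kept their call in each fit that left out 1 library. Besides Zfas1 and Atf5 these were Epop (1.68, SE 0.32, adjusted p = 0.0107), Eif1-ps1 (1.20, SE 0.17, adjusted p = 0.00295) and Faap24 (1.17, SE 0.21, adjusted p = 0.00804) among the higher. The lower ones were Eif3h, the complement protease gene Cfi (-2.24, SE 0.24, adjusted p = 0.00124), the adenosine receptor Adora1 (-2.20, SE 0.27, adjusted p = 0.00171), thrombopoietin (Thpo, -1.91, SE 0.38, adjusted p = 0.0123) and Pdgfrl (-1.82, SE 0.28, adjusted p = 0.00472). Zfas1 (ENSMUSG00000074578, chromosome 2, 167062934 to 167065862, plus strand, annotated as a processed transcript) lies next to Znfx1 on the opposite strand, which was at -0.14 (adjusted p = 0.504). Strand settings of the counting are not given in the sources used here.

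The lowest fold change belonged to Reg3b, a secreted antimicrobial lectin (-3.98, SE 0.86, adjusted p = 0.0186), whose call was lost without Apc replicate 3 (0.0533) or Apc Eif3h replicate 2 (0.0517). Its levels were 13760, 924, 6471 and 821 CPM in the 4 Apc libraries and 533, 163, 300 and 400 in Apc Eif3h. The chemokine gene Cxcl10 was at 1.87 (SE 0.41, adjusted p = 0.0188) and was lost without Apc replicate 3 (0.0634) or 4 (0.0533). Gkn3 was at -2.21 (adjusted p = 0.0198), lost without Apc replicate 4 (0.0504), Apc Eif3h replicate 2 (0.0553) or Apc Eif3h replicate 4 (0.0535). Ces2c (1.19, adjusted p = 0.0147) and Cnnm1 (1.13, adjusted p = 0.0168) were lost without Apc replicate 3 alone (0.0599 and 0.0597).

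**Figure D3:**
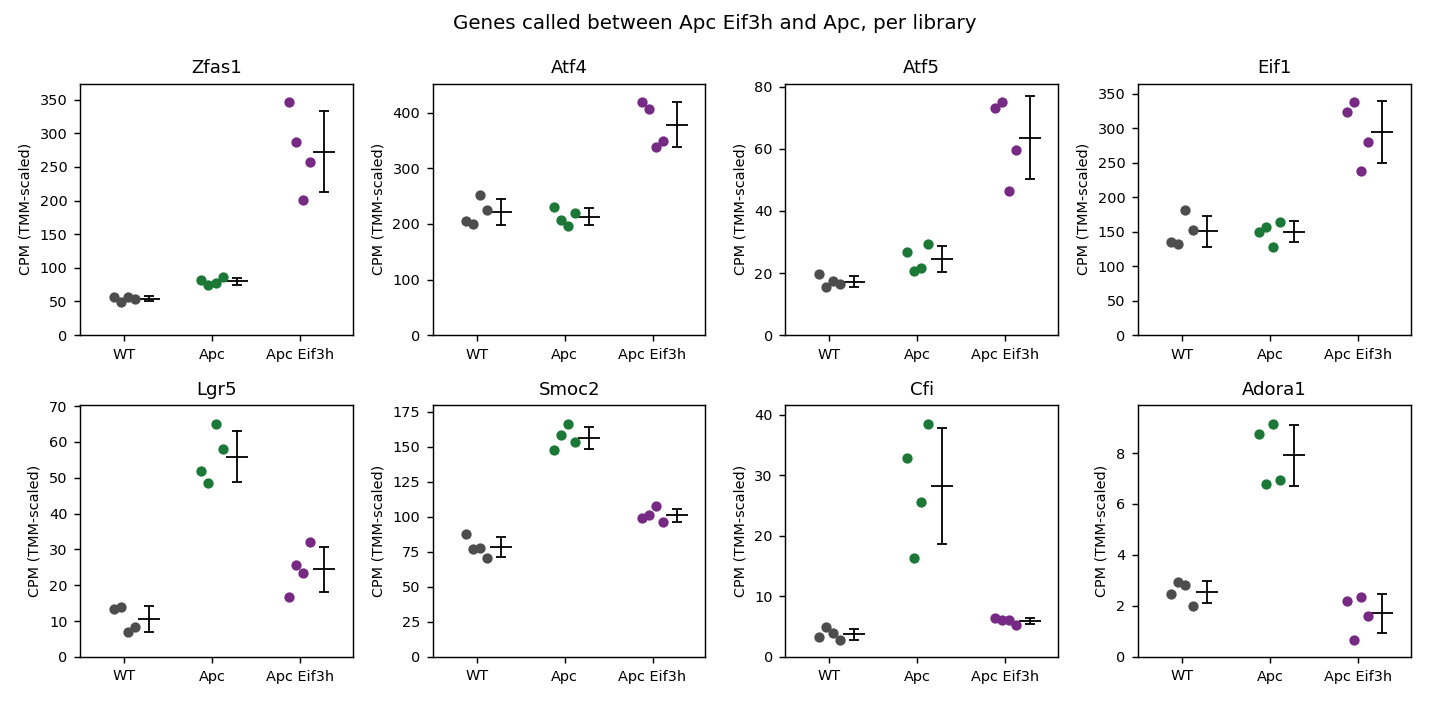
CPM after TMM scaling of 8 genes called between Apc Eif3h and Apc, one point per library in replicate order with the group mean and SD as a bar, in WT, Apc and Apc Eif3h. Zfas1, Atf4, Atf5 and Eif1 are higher in each Apc Eif3h library than in each Apc library, and Lgr5, Smoc2, Cfi and Adora1 are lower.

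Of 79 cytosolic ribosomal protein genes 69 rose in Apc Eif3h over Apc and none fell (77 adjusted over the list alone; median 0.61; camera adjusted p = 1.18e-61, but adjusted p = 0.245 with an estimated correlation). Without Apc replicate 3, 34 rose. Rps6 rose from 66.8 ± 8.40 to 116 ± 12.6 CPM (0.80, SE 0.11, adjusted p = 0.00266), Rpl35 from 62.5 ± 8.75 to 125 ± 26.1 CPM (adjusted p = 0.00443) and Rpl23 by 0.65 (SE 0.10, adjusted p = 0.00459). The share of counts on these genes was 3.342%, 3.41%, 2.283% and 2.755% in the 4 Apc Eif3h libraries. Ribosome biogenesis factors passed the list test as higher (median 0.34; camera adjusted p = 4.33e-09, adjusted p = 0.785 with an estimated correlation), although 3 of 44 rose (5 adjusted over the list alone). That number was 1 without Apc replicate 2 or Apc Eif3h replicate 1, 2 or 4, 0 without Apc replicate 3 and 20 without Apc Eif3h replicate 3. Other initiation factors were higher as a list (median 0.18; camera adjusted p = 0.000134, adjusted p = 0.73 with an estimated correlation), with 6 of 35 higher and 2 lower (14 and 2 adjusted over the list alone). Eif1, a start codon selection factor, rose from 150 ± 15.3 to 295 ± 45.1 CPM (0.98, SE 0.13, adjusted p = 0.00266). Eif5, the GTPase activator of initiation, rose by 0.77 (SE 0.11, adjusted p = 0.00304) and Eif4e3 fell by 0.58 (SE 0.10, adjusted p = 0.00605). Eif1 and Eif1-ps1 are near-identical, so the split of reads between them is uncertain. Without Apc replicate 3, 3 of these factors rose, and without Apc Eif3h replicate 3, 12 (median 0.28). Their median was 0.11 without Apc replicate 2 and 0.12 without Apc Eif3h replicate 1. A single factor, 1, fell without Apc replicate 1 or 3 or Apc Eif3h replicate 1 or 2. Among 14 eIF3 subunits Eif3h fell and 2 rose (5 adjusted over the list alone; camera adjusted p = 0.0664). The eIF3 list passed without Apc replicate 1 (0.0125) or Apc replicate 4 (0.0401), and the number that rose was 1 without Apc replicate 1, 0 without Apc replicate 2, 3 or 4 or Apc Eif3h replicate 1 or 2, and 5 without Apc Eif3h replicate 3.

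Integrated stress response targets were higher as a list (median 0.29; camera adjusted p = 0.000727, adjusted p = 0.73 with an estimated correlation), with 6 of 33 higher and 2 lower (9 and 2 adjusted over the list alone). Besides Atf4 they included the seryl-tRNA synthetase Sars (0.39, SE 0.08, adjusted p = 0.011) and Ddit3, also called CHOP (0.70, SE 0.14, adjusted p = 0.0123, but 0.0508 among males only). Without Apc replicate 2 or 3 or Apc Eif3h replicate 1, 2 or 4, 3 rose, and without Apc Eif3h replicate 3, 12. Without Apc replicate 4 or Apc Eif3h replicate 1, 2 or 4, 1 fell. The p53 targets were higher (median 0.35; camera adjusted p = 0.000134, adjusted p = 0.245 with an estimated correlation), with 6 of 25 higher and none lower (9 adjusted over the list alone). Ccng1 had the smallest p among them (0.66, adjusted p = 0.0183) and lost its call without Apc replicate 2 (0.0534) or Apc replicate 3 (0.0551). Their number was 2 without Apc replicate 1 or Apc Eif3h replicate 4, 0 without Apc replicate 2 or 3 and 1 without Apc Eif3h replicate 1 or 2. Nuclear-encoded oxidative phosphorylation genes had no called member, also adjusted over the list alone. They passed the list test as higher (median 0.12; camera adjusted p = 0.00255, adjusted p = 0.854 with an estimated correlation), and lost the call without Apc Eif3h replicate 3 (0.406, median 0.07). Without Apc Eif3h replicate 1, 1 member of that list rose and the median was 0.18. Unadjusted, 4095 genes had a p below 0.05 in this comparison, against 870 expected by chance.

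Stem cell markers were lower in Apc Eif3h than in Apc. Of 20 members 8 fell and none rose (11 adjusted over the list alone; median -0.51; camera adjusted p = 1.63e-09, adjusted p = 0.245 with an estimated correlation). The number was 3 without Apc replicate 3, 5 without Apc Eif3h replicate 2 and 4 without Apc Eif3h replicate 4. Smoc2 fell from 157 ± 7.85 to 101 ± 4.81 CPM (-0.63, SE 0.08, adjusted p = 0.00171) beside Lgr5, whereas the marker Olfm4, chosen after its value was seen, was at -0.61 with an adjusted p of 0.0892. Wnt pathway targets were lower as a list (median -0.25; camera adjusted p = 0.000633, adjusted p = 0.245 with an estimated correlation), with 4 of 25 lower and none higher (5 adjusted over the list alone). That number was 2 without Apc replicate 3 or Apc Eif3h replicate 4 and 7 without Apc Eif3h replicate 3, where the median was -0.12. Zfp703 fell by 0.43 (SE 0.08, adjusted p = 0.0106). The Wnt targets Axin2 (0.17, adjusted p = 0.553) and Myc (-0.04, adjusted p = 0.933), also chosen after their values were seen, were not called. Cell cycle genes fell in 1 of 38 members, also adjusted over the list alone (median -0.11; camera adjusted p = 0.0546), and passed the list test without Apc replicate 2 (0.000965), Apc replicate 3 (0.00572), Apc Eif3h replicate 1 (9.24e-05) or Apc Eif3h replicate 4 (0.0367). That member, Cenpf (-0.69, adjusted p = 0.0202), was lost without Apc replicate 3 (0.0714) or Apc Eif3h replicate 2 (0.0553).

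Paneth cell markers passed the list test as lower with none of 14 members called (median -0.92; camera adjusted p = 2.14e-05, adjusted p = 0.73 with an estimated correlation), and 6 fell without Apc Eif3h replicate 1 (median -1.68). Fibroblast markers did likewise, with none of 20 called (median -0.48; camera adjusted p = 0.000169, adjusted p = 0.73 with an estimated correlation). Endothelial markers, none of 15 called, passed as lower (camera adjusted p = 0.0387, adjusted p = 0.854 with an estimated correlation) but not without Apc replicate 2 (0.168), Apc replicate 4 (0.0581) or Apc Eif3h replicate 1 (0.0697), 3 (0.0693) or 4 (0.0991). For these 3 lists none was called adjusted over the list alone. Cholesterol synthesis genes fell in 3 of 25 members (6 adjusted over the list alone; median -0.20; camera adjusted p = 0.00154, adjusted p = 0.73 with an estimated correlation), with the squalene synthase gene Fdft1 at -0.42 (SE 0.08, adjusted p = 0.0107). On this list 1 fell without Apc replicate 2 or 3 or Apc Eif3h replicate 4, and 1 rose without Apc Eif3h replicate 3. Pancreatic acinar markers fell in 2 of 4 members (2 adjusted over the list alone; median -0.95; camera adjusted p = 0.00154, adjusted p = 0.245 with an estimated correlation). Rnase1 fell by 1.54 (SE 0.26, adjusted p = 0.00721), and it was the 1 member lower without Apc replicate 1, 2 or 3 or Apc Eif3h replicate 1, 2 or 4.

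The other lists did not pass the test between Apc Eif3h and Apc. Enterocyte markers (1 of 30 higher, camera adjusted p = 0.309) passed without Apc replicate 2 (0.0163) or Apc Eif3h replicate 1 (0.0455) or 2 (0.0465), and goblet cell markers (3 of 18 lower, 0.309) without Apc Eif3h replicate 1 (0.0184). Fetal-like and YAP-linked genes (4 of 23 higher, 5 adjusted over the list alone, 0.225) passed without Apc replicate 4 (0.0195) or Apc Eif3h replicate 3 (0.0314), and fatty acid oxidation genes (1 of 24 lower, 0.582) without Apc Eif3h replicate 3 (0.0301). Proximal markers (none of 11, 0.293) and T cell markers (none of 21, median 0.39, 0.291) passed without Apc Eif3h replicate 1 (0.00277 and 0.032). Macrophage markers (none of 19, 0.203) passed without Apc Eif3h replicate 2 (0.0139) and haemoglobin genes (none of 6, 0.264) without Apc Eif3h replicate 3 (0.0322). Interferon response genes had 1 of 34 higher (0.309), antimicrobial and inflammatory genes 1 higher and 2 lower of 21 (0.493) and immediate early genes 1 of 21 higher (0.387). B and plasma cell markers (none of 12, 0.546) were high in Apc Eif3h replicate 2, the library with the Ighm level given above. Enteroendocrine (0.582), tuft (0.457), unfolded protein response (0.337), mast cell (0.734), smooth muscle (0.373), neuron and glia (0.457), distal (0.797), mitochondrially encoded (0.373) and sex-linked (0.582) lists had no called member. Adjusted over the list alone, no enterocyte or immediate early gene was called and the other counts were unaltered. Few calls on these lists held without each library in turn: over the 8 fits the fetal-like list had 0 to 7 higher, the goblet list 0 to 3 lower, the fatty acid oxidation list 0 to 3 lower and the antimicrobial list 0 to 2 lower. For goblet, fatty acid oxidation, antimicrobial, distal and sex-linked lists the median, the mean and the test did not share 1 sign, as with antimicrobial genes (median 0.03, mean -0.40).

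**Figure D4:**
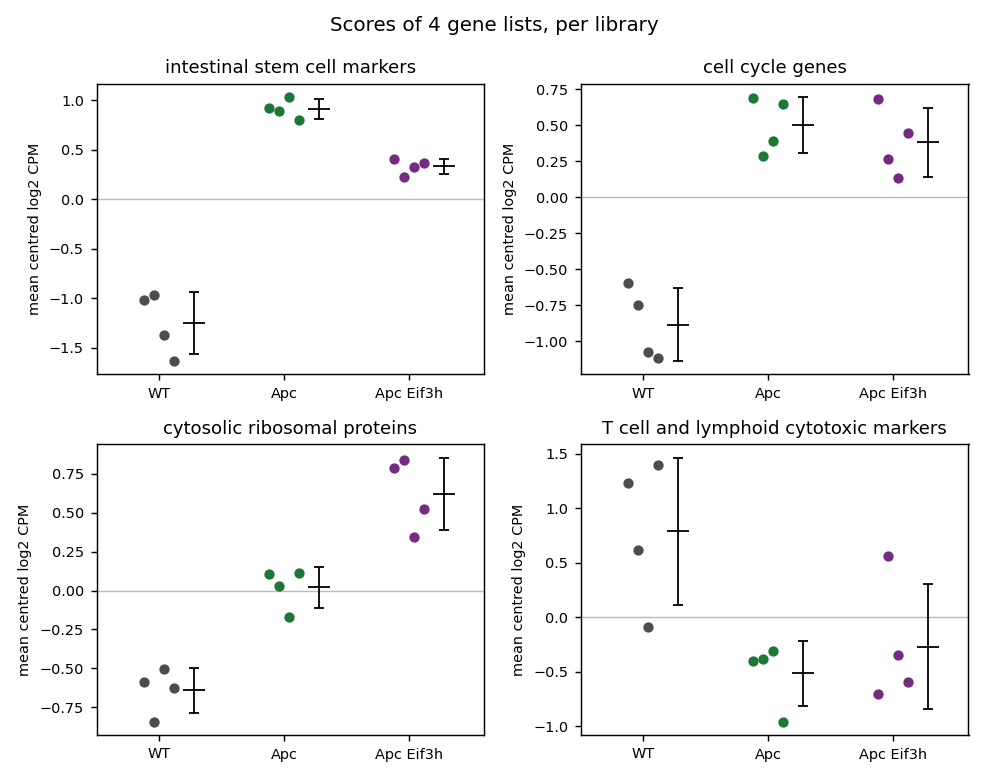
Scores of 4 gene lists (mean over members of log2 CPM centred per gene), one point per library in replicate order with the group mean and SD as a bar, in WT, Apc and Apc Eif3h. The ribosomal protein score separates Apc Eif3h from Apc (difference 0.602), the stem cell score is lower in Apc Eif3h (-0.58), cell cycle scores overlap (-0.12) and T cell scores are lower in Apc than in WT (-1.3).

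The comparison of Apc Eif3h with WT spans the labelled days as well as the genotypes. Etv4 rose by 5.05 on the log2 scale (SE 0.28, adjusted p = 9.44e-07) and Pla2g5 by 5.31 (SE 0.29, adjusted p = 9.44e-07; 64.0 ± 20.01 against 1.61 ± 0.458 CPM, n = 4 per group). Epop rose by 5.75 (SE 0.47, adjusted p = 4.24e-06; 24.7 ± 11.4 against 0.455 ± 0.133 CPM). Msx1 (5.33) and Atg9b (5.82) completed the 5 highest. Reg1 fell by 4.70 (SE 0.74, adjusted p = 0.000197; 21.1 ± 18.9 against 548 ± 289 CPM), and Gsdmc4 (-4.59), Akr1b7 (-3.83), Reg3a (-3.41) and the calcium-binding Ocm (-3.18) were the others of the 5 lowest. All 10 kept their call in each fit that left out 1 library. In total 5177 genes were higher and 4882 lower, or 57.8% of those tested, with 2053 and 1487 changed more than 2-fold. Higher genes made up 51.5% of the calls, and 67.5% with library totals only, which shifted the median log2 fold change of all genes to 0.171.

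Wnt targets rose in 19 of 25 members and fell in 2 (19 and 3 adjusted over the list alone; median 1.62; camera adjusted p = 8.16e-11, adjusted p = 0.0129 with an estimated correlation). Axin2 was at 401 ± 77.8 CPM against 68.5 ± 12.7 in WT (2.55, SE 0.16, adjusted p = 2.19e-06). Stem cell markers rose in 19 of 20 (camera adjusted p = 7.19e-13, adjusted p = 0.146 with an estimated correlation) and cell cycle genes in all 38 (6.99e-19, adjusted p = 0.359 with an estimated correlation). All 79 ribosomal protein genes rose (median 1.26; camera adjusted p = 3.44e-46, adjusted p = 0.31 with an estimated correlation), as did all 44 ribosome biogenesis factors (median 1.83; 3.03e-41, adjusted p = 0.295 with an estimated correlation). Rps6 rose by 1.47 (SE 0.11, adjusted p = 3.86e-06) and Nop2 by 1.97 (SE 0.15, adjusted p = 3.86e-06). Of the eIF3 subunits 13 rose while Eif3h fell (median 0.84; camera adjusted p = 5.7e-07, adjusted p = 0.357 with an estimated correlation), Eif3g by 1.23 (SE 0.11). Other initiation factors rose in 30 of 35 and fell in 1 (5.9e-11, adjusted p = 0.357 with an estimated correlation), with none lower without WT replicate 4 or Apc Eif3h replicate 1 or 4. Integrated stress response targets rose in 21 of 33 and fell in 5 (1.14e-06, adjusted p = 0.357 with an estimated correlation), with Gars at 1.78 (SE 0.09). Fetal-like and YAP-linked genes rose in 10 of 23 and fell in 3 (0.018, adjusted p = 0.441 with an estimated correlation), with Krt7 at 1.84 (SE 0.12) and Areg at 2.61 (SE 0.21). Adjusted over the list alone, 22 stress response targets rose and the other counts from stem cell markers on were unaltered.

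Enterocyte markers fell in 21 of 30 members (24 adjusted over the list alone; median -0.89; camera adjusted p = 1.55e-06, adjusted p = 0.441 with an estimated correlation). Goblet markers fell in 12 of 18 (0.000977, adjusted p = 0.452 with an estimated correlation) and tuft markers in 14 of 15 (0.000133, adjusted p = 0.406 with an estimated correlation). Enteroendocrine markers fell in 13 of 21 and rose in 1 (0.00286, adjusted p = 0.441 with an estimated correlation). Fatty acid oxidation genes fell in 18 of 24 and rose in 1 (0.000305, adjusted p = 0.441 with an estimated correlation), and mitochondrially encoded genes, again with a lower share of counts, fell in 10 of 13 (0.000718, adjusted p = 0.441 with an estimated correlation). Oxidative phosphorylation genes fell in 15 of 50 (11 adjusted over the list alone; 0.00339, adjusted p = 0.705 with an estimated correlation), or 24 without Apc Eif3h replicate 3, and their median of -0.20 turned to 0.0017 with library totals only. Unfolded protein response genes fell in 10 of 25 (0.00455, adjusted p = 0.525 with an estimated correlation), and the call was lost without WT replicate 1 (0.0503, with 3 higher). Adjusted over the list alone, 15 enteroendocrine, 15 tuft, 19 fatty acid oxidation and 9 unfolded protein response genes fell, with goblet and mitochondrially encoded genes unaltered. A goblet marker rose without WT replicate 3, and the number of fatty acid oxidation genes that rose was 0 without WT replicate 2 or 4 or Apc Eif3h replicate 3 or 4 and 2 without WT replicate 3.

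T cell markers fell in 12 of 21 members (median -1.08; camera adjusted p = 0.000977, adjusted p = 0.525 with an estimated correlation), or 19 without Apc Eif3h replicate 2, with Gzma at -2.02 (SE 0.30). Interferon response genes fell in 12 of 34 (0.00286, adjusted p = 0.585 with an estimated correlation), with B2m at -1.12 (SE 0.18). The interferon call was lost without WT replicate 1 (0.0601, 8 lower and 1 higher), while 19 were lower without WT replicate 3 and 8 lower and 1 higher without Apc Eif3h replicate 4. Antimicrobial and inflammatory genes fell in 11 of 21 and rose in 1 (0.00692, adjusted p = 0.362 with an estimated correlation), with Pigr at -1.90 (SE 0.31). Macrophage markers fell in 16 of 19 (0.00042, adjusted p = 0.489 with an estimated correlation), with Adgre1 at -1.46 (SE 0.23). Fibroblast markers fell in 15 of 20 (18 adjusted over the list alone; 0.000133, adjusted p = 0.441 with an estimated correlation), with Dpt at -1.40 (SE 0.18). Smooth muscle (11 of 15; 0.00194, adjusted p = 0.441 with an estimated correlation), endothelial (12 of 15; 0.00175, adjusted p = 0.489 with an estimated correlation) and neuron and glia markers (12 of 15; 0.000792, adjusted p = 0.362 with an estimated correlation) were lower as well. Adjusted over the list alone, 10 interferon, 13 endothelial and 13 neuron and glia genes fell and 1 macrophage and 1 neuron and glia gene rose, the other counts being unaltered. The antimicrobial gene that rose was not called without WT replicate 2, 1 macrophage marker rose without WT replicate 1 or Apc Eif3h replicate 3, and 1 neuron and glia marker without Apc Eif3h replicate 1.

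The lists not called between Apc Eif3h and WT were p53 targets (11 higher and 6 lower of 25; camera adjusted p = 0.201), cholesterol synthesis (12 and 4 of 25; 0.0599), and Paneth genes (1 of 14 higher; 0.663). Others were B and plasma cell (1 and 4 of 12; 0.253), mast cell (1 of 4 lower; 0.505), proximal (2 and 5 of 11; 0.405), and distal genes (1 and 4 of 11; 0.0952). The last were acinar (2 of 4 lower; 0.178), haemoglobin (none of 6; 0.497), immediate early (7 and 3 of 21; 0.653) and sex-linked genes (1 of 5 lower; 0.887). Cholesterol synthesis passed without WT replicate 3 (0.0146), WT replicate 4 (0.0457) or Apc Eif3h replicate 2 (0.0457), 3 (0.0476) or 4 (0.0449), and distal markers passed without Apc Eif3h replicate 1 (0.039). Without Apc Eif3h replicate 2, the library with high Ighm, 11 of the B and plasma cell markers were lower and the list passed (0.00232). Of the B and plasma cell markers 2 were lower without WT replicate 1, and the number higher was 0 without any 1 WT library and 2 without Apc Eif3h replicate 1, 3 or 4. Without Apc Eif3h replicate 1, 4 Paneth and 3 proximal markers were lower, and without Apc Eif3h replicate 2, 3 proximal markers. The sex-linked call was lost without WT replicate 4 or any 1 Apc Eif3h library, and without WT replicate 3, 2 distal markers were higher. Adjusted over the list alone, 13 cholesterol synthesis genes rose and no sex-linked gene was called. Aen (2.26, SE 0.23) and Bax (1.02, SE 0.12), p53 targets with roles in cell death, were higher than in WT. The median, the mean and the test did not share 1 sign for the Paneth, B and plasma cell, proximal and sex-linked lists.

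Genes called in both steps were counted to see how far the second deficiency moved the genes that changed in Apc. Of the genes higher in Apc than in WT, 249 were lower in Apc Eif3h than in Apc, and 109 genes went down and then up. Independent lists of these sizes would share 133.8 and 179.1, but both steps use the same Apc libraries and so are not independent. With the Apc libraries split into 2 and 2, one pair for each step, 6 such splits gave 18 to 92 and 3 to 18, with 61 to 701 genes called between Apc Eif3h and Apc in place of 1226. These ranges therefore cannot be set against the full counts. Another 358 genes were higher in both steps (205.9 for independent lists) and 37 lower in both (116.4), with 7 to 332 and 0 to 23 over the same 6 splits. Over all genes the covariance of the 2 sets of log2 fold changes was -0.0659, against a mean of -0.0383 in 20 simulations of unchanged groups sharing the Apc libraries, and lay between -0.0864 and 0.0379 over the splits. Their correlation was -0.173, against -0.49 in the simulations, and lay between -0.225 and 0.0801 over the splits. The shared Apc libraries alone give the simulated correlation, and unrelated changes in either step weaken it. The gap between these 2 correlations therefore does not show how far the second step moved genes back. The count of 249 was 157 without Apc replicate 1, 104 without Apc replicate 3, 144 without Apc Eif3h replicate 2 and 151 without Apc Eif3h replicate 4. The count of 109 was 70 without WT replicate 4, 43 without Apc replicate 1, 29 without Apc replicate 3, 37 without Apc replicate 4, 68 without Apc Eif3h replicate 2 and 64 without Apc Eif3h replicate 4.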

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

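The tests of scaling, of random genes no longer than each member, of the share of proliferating cells, of the epithelial share and of the day of harvest were chosen only after the result was seen. The tests of other splits, of random lists matched on length and of single libraries were set down before their results.

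Other splits of the libraries argue against chance for the counts of called genes in all 3 comparisons, but do not exclude it. In edgeR fits of the 8 libraries compared, 9199 genes were called for Apc against WT and at most 0 in the other splits of the same libraries, 977 for Apc Eif3h against Apc and at most 1 in the others, and 9107 for Apc Eif3h against WT and at most 0 in the others. Of 35 splits into 4 and 4, 1 reached the real count each time, the real split itself, which is the smallest share possible. Every other split mixes libraries of both groups, so a real group difference widens the spread there and lowers the calls. The size of the gap therefore does not measure how unlikely chance is.

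Ribosomal protein genes were higher in Apc Eif3h than in Apc, with a score difference of 0.602 (exact permutation p = 0.0286 over 70 arrangements, the smallest they can give), although the list's call is lost with an estimated correlation (adjusted p = 0.245). Against short transcripts as the cause, 0 of 10000 random lists near the members in length and expression reached the list's median by exon length (0.6135, highest 0.2296) or principal transcript (0.6173 for 74 of 79 genes, highest 0.1947), and, since these random genes were longer (medians of 2235 against 1770 and 892 against 680.5 bases), 0 of 10000 did so with random genes no longer than each member (highest 0.2171 by exon length, and 0.2142 by principal transcript for 71 genes). The random genes were drawn independently, whereas ribosomal protein genes move together. These counts therefore show how other genes of such length behaved, not how rare the list's median is. Against scaling between libraries, the median was at least 0.588 with RLE factors or library totals. Against a larger share of proliferating crypt cells, the cell cycle score did not rise (-0.12, exact permutation p = 0.486). The cell cycle score minus the ribosomal protein score differed by -0.722 (exact permutation p = 0.0286), lower in every Apc Eif3h library than in every Apc library. That difference mostly restates the rise of the ribosomal protein score. A response to the loss of Eif3h is a hypothesis that stays open, as do RNA quality and reads shared with pseudogenes, which were not tested, and part of the difference may come from any of these.

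Stem cell markers were lower in Apc Eif3h than in Apc, with a score difference of -0.58 (exact permutation p = 0.0286). Against a single library as the cause, the list's median stayed at -0.465 or lower and its call held in all 8 fits that left out 1 library, although it is lost with an estimated correlation (adjusted p = 0.245). A smaller share of proliferating crypt cells cannot be told apart from a change within stem cells. The cell cycle score alone differed by -0.12 and did not separate the groups (exact permutation p = 0.486). The stem cell score minus the cell cycle score, without shared members, differed by -0.46 but did not separate the groups (exact permutation p = 0.0571). Loss of Eif3h may lower these markers in these or other ways, which stays a hypothesis.

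Markers of non-epithelial cells were lower in Apc than in WT, with score differences of -1.3 for T cells (exact permutation p = 0.0286) and -0.373 for fibroblasts (exact permutation p = 0.171), but both list calls are lost with an estimated correlation (adjusted p = 0.511 and 0.564) and that of fibroblasts also without WT replicate 1 (0.0778). For a larger epithelial share alone, the T cell score minus the fibroblast score differed by -0.93 (exact permutation p = 0.0286), lower in every Apc library than in every WT library. These lists were paired after the result was seen. They had the largest and smallest median falls (-1.49 and -0.32) of the called lists of non-epithelial markers. The p takes no account of that choice, so this test cannot decide against such a share. A change within T cells or their number stays open beside such a share. The day of harvest cannot be told apart from the genotype, since 0 of the WT libraries carry day 4 in their labels. Deletion of Apc itself is an open explanation that was not tested.

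The remaining results are groups of 4 libraries in which 1 library lay far from the other 3, measured as its gap to the nearest divided by the group's range. For genes this ratio was taken on log2 CPM, and the values given beside it are CPM. Chance gives this in about 1 in 20 groups. Of 546 groups tested 26 stood apart, against 27.3 expected by chance, so single cases carry little weight, but 8 of the 26 fell on Apc Eif3h replicate 3. That library also had the highest Eif3h level of its group (54.6 CPM) and the highest enterocyte score (0.199 against -0.477 to -0.275). Whether its deletion was less complete, or its cell make-up differed, was not tested. Genes that move together are not separate cases, so these 8 may not be independent. Another 4 each fell on Apc Eif3h replicate 2 and WT replicate 1, 3 on Apc replicate 4, 2 on Apc Eif3h replicate 1 and 0 or 1 on each of the others.

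Apc Eif3h replicate 3 was higher than the rest of its group in Ces2a (569 against 116 to 152 CPM, ratio 0.833), Cyp2b10 (140 against 24.3 to 30.5, 0.87), Dgat1 (766 against 452 to 490, 0.846), Gzma (42.1 against 31.4 to 32.2, 0.912) and Msx1 (35.6 against 15.96 to 17.4, 0.895). It was lower in Atg9b (2.67 against 21.8 to 29.3, 0.874), Phgdh (21.2 against 36.01 to 38.1, 0.905) and Snhg15 (20.9 against 30.9 to 32.2, 0.902). Apc Eif3h replicate 2 was higher in Cd79a (83.8 against 1.68 to 1.87 CPM, 0.973), Ighm (462 against 8.56 to 10.7, 0.945) and the B and plasma cell score (2.34 against -1.15 to -0.729, 0.878), and lower in Olfm4 (1013 against 1260 to 1275, 0.948). Apc Eif3h replicate 1 was higher in Habp2 (12.8 against 4.29 to 4.53, 0.95) and lower in Alox5 (1.07 against 1.67 to 1.74, 0.914).

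In Apc, replicate 3 was lower in Fbl (46.1 against 58.3 to 60.6 CPM, 0.859), and replicate 4 was lower in Reg3a (7.32 against 39.4 to 49.9, 0.877), in the T cell score (-0.96 against -0.406 to -0.311, 0.854) and in the share of counts on the 20 highest genes (8.14% against 9.28% to 9.38%, 0.923). Apc replicate 1 had the lowest library total (10483112 against 17238222 to 18621953 counts, 0.83) and Apc replicate 2 the highest smooth muscle score (0.00744 against -0.137 to -0.124, 0.91). In WT, replicate 1 was higher in Eif3b (133.5 against 117 to 119, 0.836) and Jchain (2597 against 751 to 870, 0.882) and lower in Prss27 (0.387 against 0.832 to 0.926, 0.869) and Uchl1 (11.2 against 12.8 to 13.1, 0.858). WT replicate 2 had the highest total (14589963 against 13915889 to 14003835 counts, 0.881), and WT replicate 4 was lower in Cbx3-ps8 (0.0824 against 1.21 to 1.25, 0.985).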

How the results depend on the processing

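Of the alternatives here, none was chosen after the result was seen, and no called list or named gene passed the test in the opposite direction under any of them. With RLE factors and with the stricter filter, the counts of called genes stayed within 1.5 times and all 108 list results kept their call status, and 279 and 280 of the named-gene results did. With an estimated correlation the lists called were 2 higher and 0 lower for Apc against WT, 0 and 0 for Apc Eif3h against Apc, and 1 and 0 for Apc Eif3h against WT, so 60 of 108 list results lost their call. By fry 2 lists were higher and 3 lower for Apc Eif3h against Apc. The higher ones were ribosomal proteins and p53 targets (fry adjusted p = 0.0123 for each). The lower ones were stem cell markers (fry adjusted p = 0.0201), Wnt targets (0.0261) and acinar markers (0.0123). Fry does not compare a list with other genes. With a fold change above 2 as well, 1627 genes were higher and 1137 lower in Apc against WT, 77 and 138 in Apc Eif3h against Apc, and 2053 and 1487 in Apc Eif3h against WT, by construction of the threshold. Library totals as the only scaling gave 2393 lower genes in Apc against WT, 485 higher in Apc Eif3h against Apc, 3175 lower in Apc Eif3h against WT and 48 that went down and then up. Testing without a filter gave 306 lower in Apc Eif3h against Apc and 51 that went down and then up. That last count was 69 with sex as a covariate and 183 with DESeq2. Among male libraries only, 400 genes were higher and 259 lower in Apc Eif3h against Apc, 128 went up and then down and 20 down and then up, with fewer libraries. For these other changes the cause was not tested.

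Leaving out 1 library gave 242 (without Apc replicate 3) to 1152 (without Apc Eif3h replicate 3) higher and 164 to 615 (the same libraries) lower genes in Apc Eif3h against Apc. It gave 104 (without Apc replicate 3) to 255 (without WT replicate 1) genes that went up and then down and 29 (without Apc replicate 3) to 107 (without WT replicate 2) that went down and then up. Over these fits and the 3 contrasts together, call status was unchanged in 2088 results for named genes, lost in 175 and gained in 1. Most of the losses were in Apc Eif3h against Apc. There 10 of the 20 genes with the highest and lowest fold changes kept their call in every such fit. All 20 did so in Apc against WT and all 10 in Apc Eif3h against WT. Of the 1226 genes called between Apc Eif3h and Apc, 1192 were also called by DESeq2, 1129 with RLE factors, 906 with sex as a covariate, 886 with library totals, 853 in a fit of the 2 groups alone, 786 without a filter and 615 among males.

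Replicate numbers recur in all groups but did not pair the libraries: 3 of 12 same-number pairs had a correlation of deviations above 0.1 (range -0.142 to 0.236), and 5 of 24 best matches had the same number. With the replicate block 594 genes were higher and 399 lower in Apc Eif3h against Apc, 883 of them shared with the 1226, and 66 went down and then up (68 for the replicate block with RLE factors). Small changes can be missed at this depth and number of libraries, which were not varied. At a log2 fold change of 0.5, 10.4% of changed genes were recovered in the simulation for Apc Eif3h against Apc. Fewer genes were changed there than were called in the data, so this share may understate the recovery.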

Other observations

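The lists of TOP mRNAs and of small nucleolar RNA host genes were chosen after the rise of ribosomal protein genes and of Zfas1 was seen, with each test set down before its own result.

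TOP mRNAs share a pyrimidine tract at their start that ties them to ribosomal protein mRNAs. Of 13 such mRNAs outside the list of ribosomal protein genes, 6 rose in Apc Eif3h over Apc (9 adjusted over the list alone) and 12 had a positive fold change. The median was 0.556 (camera p = 7.81e-13, and p = 0.0171 with an estimated correlation, both unadjusted). The unadjusted camera p of the ribosomal protein list with an estimated correlation was similar (0.0173), and its call was lost after adjustment over the lists (0.245). Elongation factor genes Eef1b2 (0.92, adjusted p = 0.00295) and Eef1g (0.68, adjusted p = 0.00808) and Tpt1 (0.64, adjusted p = 0.0079) kept their call in each fit that left out 1 library. Rack1 (0.64), whose product is part of the small ribosomal subunit, lost its call without Apc replicate 3 (adjusted p = 0.0567) and Eef2 (0.69) without Apc replicate 2 (0.0538), Apc replicate 3 (0.0755) or Apc Eif3h replicate 4 (0.0503). Eef1a1 (0.71, adjusted p = 0.0326) kept it only without Apc Eif3h replicate 3. A hypothesis is a response shared by other TOP mRNAs, for which 0 of 10000 random lists matched on expression and length (median 3042 against 2665 bases) reached the list's median (highest 0.282), and it may include the ribosomal protein genes. It was found and tested on the same libraries, and Npm1 on this list is also a ribosome biogenesis factor. Random genes were drawn independently, so the count of 0 does not allow for members of a list that move together.

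Zfas1 is 1 of several noncoding hosts of small nucleolar RNAs, whose spliced transcripts are kept low by nonsense-mediated decay, a process coupled to translation. Of 12 other hosts tested 5 rose (8 adjusted over the list alone), 1 fell and 11 had a positive fold change. The median was 0.472 (camera p = 3.67e-08, and p = 0.0434 with an estimated correlation, both unadjusted). Gas5 (0.87, adjusted p = 0.00407), Snhg6 (0.77, adjusted p = 0.0047), Epb41l4aos (0.83, adjusted p = 0.00767) and Snhg15 (0.81, adjusted p = 0.00924) kept their call in each fit that left out 1 library. Snhg1 (0.61, adjusted p = 0.0148) lost it without Apc replicate 3 (0.0599), and Snhg18, the 1 that fell (-0.41, adjusted p = 0.0457), kept it only without Apc replicate 1 or Apc Eif3h replicate 3. For a rise of small nucleolar RNA host genes as a class, 0 of 10000 matched random lists (median 1695 against 1608 bases) reached the list's median (highest 0.4552). That count again does not allow for hosts that move together. Many of these hosts are also TOP mRNAs, so both lists may follow 1 response, and decay was not measured here.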
